A study of Mus musculus with 8 samples.

How the data were processed

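RNA from the hypothalamus of male mice was measured on Illumina MouseRef-8 v2 bead arrays, in 8 samples with 1 array each. The labels give 3 samples of streptozotocin-induced diabetes (STZ, replicates 1, 2 and 3), 2 saline controls (replicates 4 and 5) and 3 samples of STZ with a continuous leptin infusion (replicates 6, 7 and 8), at an age of 12 to 15 weeks and with the strain given only as mixed. Hypothalamic blocks were dissected fresh, RNA was isolated with TRI Reagent, and 300 ng per sample was amplified to biotinylated cRNA. The labels do not say whether each array held RNA of a separate animal, so the p-values measure only the spread between these samples. The description of STZ replicate 3 carries the number 1, as that of STZ replicate 1 does, while the saline descriptions carry 2 and 3. Its title and source name both say STZ, and it was analysed as STZ.

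The deposited raw table holds a bead-summary intensity per probe and array, on a linear scale, without background subtraction or normalization between arrays. Per the file headers, each intensity is followed by a detection p-value of the same probe on the same array. The authors' processed table holds log2 values. Its software is not given in the sources used here. Each of its columns had a median of 6.90 and the same set of values, as after quantile normalization, no centring of probes was seen, and each column ranked the probes as the raw column of its own sample did (Spearman correlation 1.000, highest with any other sample 0.957). The raw intensities were the main input and the processed table an alternative.

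Intensities were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3, which takes the negative controls from the detection p-values, adds an offset of 16, normalizes quantiles between arrays and takes log2. Of 25697 probes, 15494 were kept, each with a detection p-value under 0.05 on at least 2 arrays. Median raw intensity per array lay between 117.2 and 127.5, and between 13608 and 14776 probes were detected per array (53.0 to 57.5 percent). The number of arrays, not the number of probes, limits the precision. The probe table gave 1 gene symbol to 23978 probes and none to 1719. Symbols were brought up to date through their Entrez identifiers, and a RefSeq gene table of mouse assembly GRCm38.p6 served only for names and for the order of genes along the chromosomes. The kept probes with a symbol numbered 14615 and stood for 10703 genes.

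A linear model with 3 group means was fitted to all 8 arrays with lmFit and eBayes (5 residual and 3.94 prior degrees of freedom). Its contrasts were STZ minus saline, STZ with leptin minus STZ, and STZ with leptin minus saline. P-values were adjusted with the Benjamini-Hochberg method over the kept probes, and a probe passed at an adjusted p of 0.05 with no minimum fold. Errors beside log2 differences are the moderated standard errors of limma. A gene is represented by its kept probe of highest mean signal. Where a probe was undetected on all arrays of the dimmer group, the fold is given as a lower bound: the dimmer group's value on each array was replaced by the lowest normalized value of a detected probe on that array, or by the probe's own value where higher.

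A probe counted as reversed when it passed in STZ minus saline and in STZ with leptin minus STZ with opposite signs. Because both contrasts share the STZ arrays, noise in those arrays alone produces opposite signs. Data without any group effect were therefore simulated 100 times with the residual variances of the fit, and the reversed probes were counted in the same way. In a further 100 simulations, chosen after the results were seen, the fitted STZ differences of the probes that passed were given to the STZ and the leptin arrays alike. The noise was drawn independently for each probe. The 3 STZ arrays cannot be divided into separate sets of at least 2 for the contrasts.

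Gene lists were written before the data were examined, 38 in number with 955 entries, of which 837 had a probe. They covered hypothalamic peptides and receptors, hormone-responsive and metabolic genes, stress and immune genes, and markers of cell types and neighbouring brain regions. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 38 lists of a contrast. Named genes followed rules fixed at the same time. They were the 12 genes with the highest and the 12 with the lowest log2 difference among those that passed, members of the lists that passed with the lowest p-values in the direction of the list (at most 4 of a list), a fixed set of genes central to leptin action, and the reversed genes with the lowest p-values (at most 20). Genes outside these rules appear only in the closing section, apart from the pituitary hormones Gh and Prl and members that complete the count of a list. List members were also counted with the p-values adjusted over the list alone, and list medians were also computed with undetected members at their bound.

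The fit, the list test and the reversal count were tested on simulated log2 values of 15494 probes, of which some were given a change. Background correction, normalization and the detection filter were not part of this test, and the noise was drawn independently for each probe. In STZ minus saline the fit recovered 16, 54, 98 and 96 percent of the 50 probes changed at each of 1.5, 2, 4 and 8 times, with 2 false calls. In STZ with leptin minus STZ it recovered 12, 64, 98 and 98 percent, with 8 false calls. Of 200 planted reversed probes, 123 were recovered and 0 were called wrongly.

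The alternatives written before the data were examined were the authors' processed values, no background correction, normexp with an offset of 50, median centring, cyclic loess, no detection filter, detection under 0.01 on all 8 arrays, a robust variance trend, array quality weights, fits of only the groups compared, the described replicate number as a block, STZ replicate 3 taken as saline, leaving out each sample in turn, and the mean of all probes of a gene. None was added later. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.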

Results

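In the hypothalamus of STZ mice 23 of 26 measured interferon and MHC class I genes rose against saline. With central leptin infusion 17 of the 26 were lower than in STZ and 8 were higher than in saline, and none of these list calls held with an estimated correlation (adjusted p = 0.095, 0.42 and 0.66). Lcn2, a secreted iron-trap protein of inflammation, was undetected in saline and lay at least 345-fold above it in STZ and at least 72.9-fold with leptin (n = 3 STZ, 2 saline, 3 STZ with leptin). STZ replicate 3 was taken as STZ from its title. It correlated at 0.979 and 0.988 with the other STZ samples and at 0.957 and 0.962 with the saline samples, and its genes of the interferon list lay a median 2.98 log2 units above saline. Such correlations do not sort every sample by group. STZ replicate 1 correlated at 0.969 with STZ replicate 2 and at 0.971 with saline replicate 4.

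In STZ against saline (n = 3 and 2), the highest rises included Saa3 and Lcn2. Saa3, an acute-phase serum amyloid, rose 347-fold (8.44 ± 0.51 log2 units, adjusted p = 4.4e-05 in limma), and Lcn2 rose at least 345-fold. The chemokines Cxcl9, Ccl5 and Cxcl10 rose at least 95.4-fold, 105.1-fold and 68.6-fold. The interferon-induced GTPases Igtp and Gbp2 rose 59.9-fold (5.90 ± 0.25) and 30.6-fold (4.94 ± 0.25). Socs3, a STAT3-induced inhibitor of cytokine and leptin signalling, rose 14.0-fold (3.81 ± 0.34, adjusted p = 0.00025).

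Falls were smaller. Gkn3 fell by 1.36 ± 0.16 log2 units, the oligodendrocyte gene Enpp6 fell by 1.03 ± 0.15 and the chemokine Cxcl12 fell by 1.00 ± 0.16. Bdnf, a growth factor that lowers food intake, fell by 0.83 ± 0.16. Without saline replicate 4 or 5 the adjusted p was 0.051 or 0.062 for Enpp6, 0.079 or 0.076 for Cxcl12 and 0.17 or 0.16 for Bdnf, and without STZ replicate 2 or 3 it was 0.062 or 0.079 for Bdnf. With the mean of all probes of a gene it was 0.19 for Cxcl12 and 0.054 for Bdnf.

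The neuropeptides that carry leptin's effect on feeding did not pass in this comparison in the main fit. Cartpt differed by -1.10 ± 0.29 (adjusted p = 0.079, and 0.013 with array weights), Pmch by -0.39 ± 0.18, Hcrt by -0.72 ± 0.32, Npy by 0.23 ± 0.39 and Trh by -0.26 ± 0.23. Avp, the antidiuretic hormone, differed by 1.14 ± 0.37 (adjusted p = 0.17, and 0.037 with array weights). Pomc differed by 0.42 ± 1.40, and STZ replicate 2 held it at 11.88 against 6.69 and 5.97 in the other STZ samples, together with the pituitary hormones Gh (14.98) and Prl (14.93). Without STZ replicate 2, Pomc differed by -1.44 from saline, with an adjusted p of 0.029. Probes of Lepr and Crh were detected on 0 arrays, and no probe was named Agrp.

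By gene list, 23 of 26 measured interferon and MHC class I genes rose and 0 fell, with a median of 2.87 log2 units (2.75 with undetected members at their bound, adjusted p = 0.095 with an estimated correlation). All 26 rose when adjusted over the list alone. Of 24 cytokine and NF-kB genes, 16 rose (Tlr2 by 3.52, Myd88 by 1.95) and Cxcl12 fell, with a median of 2.01 (1.84 at the bound, adjusted p = 0.17 with an estimated correlation, and 20 higher and 1 lower adjusted over the list alone). Of 21 markers of microglia and macrophages, 13 rose, among them the complement genes C1qa, C1qb and C1qc by 2.28, 2.70 and 2.97, with a median of 1.90 (adjusted p = 0.095 with an estimated correlation, and 17 higher adjusted over the list alone).

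Of 23 leptin receptor and STAT3 target genes, 8 rose, including Socs3 and Irf9 (2.11 ± 0.15), with a median of 0.50 (0.43 at the bound, adjusted p = 0.17 with an estimated correlation, and 10 higher adjusted over the list alone). These targets also answer to cytokines. Among 25 glucocorticoid-induced genes, Lcn2, Plin4 (2.19) and Mertk (0.66) rose, with a median of 0.46 (adjusted p = 0.46 with an estimated correlation, and 5 higher adjusted over the list alone). Plin4 had an adjusted p in limma of 0.060 without a detection filter, 0.053 with a robust trend and 0.055 with only the groups compared. Mertk had 0.0501 under median centring and 0.073 with only the groups compared. With the replicate number as a block they had 0.096 and 0.16. The adjusted p was 0.16 and 0.20 for Plin4 and 0.21 and 0.17 for Mertk without saline replicates 4 and 5, 0.092 and 0.079 without STZ replicate 3, and 0.066 for Mertk without STZ replicate 2. The 9 blood cell markers passed as a list with 0 members passing alone and a median of 0.69 (0.56 at the bound, adjusted p = 0.63 with an estimated correlation, and 3 higher adjusted over the list alone). S100a8 among them, undetected in saline, lay at least 15.7-fold higher without passing in the main fit (adjusted p = 0.12, and 0.0015 with array weights). Without STZ replicate 2 the adjusted p of the blood list was 0.20, and it was 0.36 among probes detected under 0.01 on all arrays.

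Lists of neurons and hypothalamic signalling lay slightly lower, against a median of -0.09 for all probes (-0.19 under median centring). Of 24 genes of the list of hypothalamic receptors for metabolic signals, Bdnf fell and Crhr1 fell by 0.67 ± 0.14, with a median of -0.31 (-0.31 at the bound, adjusted p = 0.17 with an estimated correlation, and 2 lower adjusted over the list alone). Crhr1 did not pass in limma in the authors' processed values (adjusted p = 0.081), without background correction (0.087) or with normexp (0.077). It also missed with cyclic loess (0.067), a robust trend (0.094), only the groups compared (0.11) and the replicate number as a block (0.28). The list's adjusted p was 0.092 among probes detected under 0.01 on all arrays, and that of Crhr1 lay between 0.054 and 0.27 without any 1 sample other than STZ replicate 1. Of 13 neuron markers 0 passed, with a median of -0.28 (Nefm -0.48 ± 0.15, Rbfox3 -0.43 ± 0.14, adjusted p = 0.17 for the list with an estimated correlation and 0.054 without saline replicate 5). Of 13 feeding-lowering peptides, Bdnf fell, with a median of -0.26 (adjusted p = 0.46 with an estimated correlation, and 2 lower adjusted over the list alone). That list's adjusted p was 0.15 without STZ replicate 1 and 0.098 without saline replicate 5, and 0.092 under median centring, 0.062 with array weights, 0.12 among probes detected under 0.01 on all arrays and 0.057 with the mean of all probes of a gene.

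In total 665 of 15494 probes passed in limma, 617 higher and 48 lower in STZ, for 495 genes, and 515 of them changed at least 2-fold. The count was 1032 without STZ replicate 1 (162 lower), 425 without STZ replicate 3 (20 lower), 277 without saline replicate 4 (3 lower), 316 without saline replicate 5 (2 lower), 1662 with array weights (593 lower), 332 among probes detected under 0.01 on all arrays (29 lower), 647 under median centring (72 lower), 693 with cyclic loess (23 lower), and 0 in limma with STZ replicate 3 taken as saline (893 at an unadjusted p under 0.05). Of 38 lists 9 passed, 18 without STZ replicate 1, and 0 with an estimated correlation in camera (6 at an unadjusted p under 0.05, and 8 in fry).

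**Figure D1:**
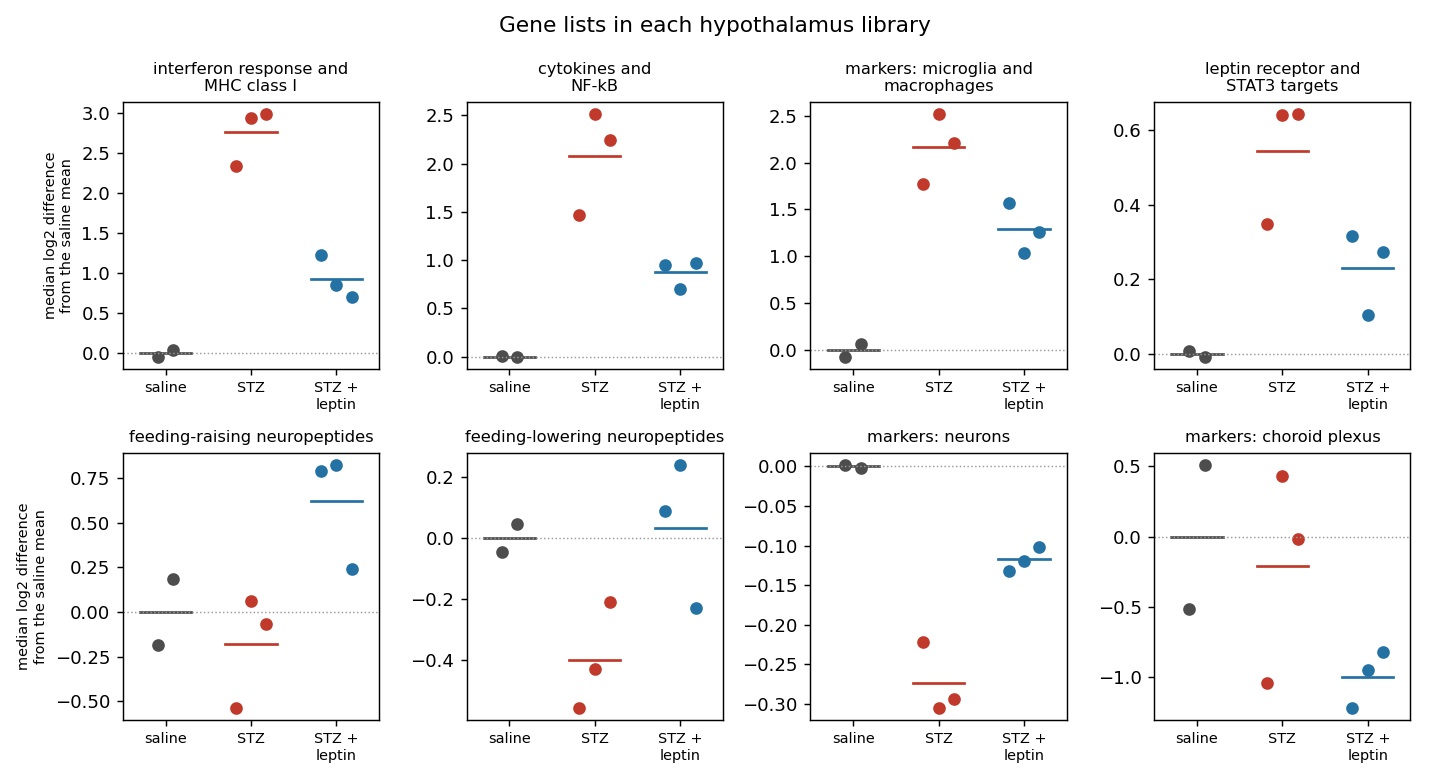
Median log2 difference from the saline mean of the measured members of 8 gene lists. Each point is 1 library and each bar the mean of a group. Immune lists lie high in all 3 STZ libraries and between STZ and saline with leptin.

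In STZ with leptin against STZ (n = 3 and 3), many of the interferon-induced genes fell, and so did the chemokines Cxcl9 and Cxcl10. Igtp fell by 3.85 ± 0.23 log2 units (adjusted p = 3.0e-05 in limma), Cxcl9 fell by 4.39 ± 0.65, Gbp2 fell by 3.07 ± 0.22, Irf1 fell by 2.81 ± 0.18 and Cxcl10 fell by 3.10 ± 0.37. Socs3 fell by 1.89 ± 0.30 (adjusted p = 0.0079). P2ry12, a receptor of resting microglia, fell by 2.32 ± 0.20 after a difference of -0.13 between STZ and saline. Its probe belongs to a set of 112 that stood at 1 level in STZ and saline and at another with leptin, in which sequence variants under the probes are a candidate source, so this fall may not be one of expression.

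Some hypothalamic peptides rose. Cartpt, made by neurons that leptin activates, rose 2.43-fold (1.28 ± 0.26, adjusted p = 0.022), Pmch rose 1.84-fold (0.88 ± 0.16), Gal rose 2.65-fold (1.41 ± 0.29) and Hcrt rose 2.30-fold (1.20 ± 0.29, adjusted p = 0.045). Without leptin replicate 6 or 7 the adjusted p was 0.069 or 0.074 for Cartpt, 0.062 or 0.072 for Gal and 0.13 or 0.14 for Hcrt, and 0.056 for Pmch without replicate 6. Without STZ replicate 3 it was 0.068 for Cartpt, 0.076 for Gal and 0.14 for Hcrt, and without STZ replicate 1 it was 0.090 for Hcrt. For Hcrt it was also 0.074 and 0.073 without saline replicates 4 and 5, 0.069 with cyclic loess and 0.081 without a detection filter. With the replicate number as a block none of these peptides passed in limma. Their adjusted p was then 0.053 (Cartpt), 0.066 (Pmch), 0.077 (Gal) and 0.096 (Hcrt). Hcrt had 0.054 with a robust trend and 0.074 with only the groups compared. Npy differed by 0.27 ± 0.35, Trh by 0.31 ± 0.21, Avp by -0.44 ± 0.33 and Oxt by 0.27 ± 0.23. Pomc differed by -0.04 ± 1.25, and by 1.82 without STZ replicate 2, with an adjusted p of 0.0074.

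The highest rises were of another kind. Csrp1 rose 65.0-fold (6.02 ± 0.17), from 6.44 in STZ, with 6.58 in saline. Pdrg1 rose at least 29.0-fold and Sspn at least 22.4-fold, and the Y-linked Eif2s3y rose at least 12.8-fold. Prkag2 fell at least 11.3-fold. These probes too belong to the set of 112. Gdpd3 fell from 11.22 in STZ, with 10.26 in saline, to about background, with detection on 1 of 3 leptin arrays. It lies outside the set, which allows at most 0.5 log2 units between STZ and saline. Its pattern is otherwise alike, so the same doubt applies to it.

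By list, 17 of 26 interferon and MHC class I genes fell (median -1.68, and 25 lower adjusted over the list alone), 8 of 24 cytokine and NF-kB genes fell (Tlr2 fell by 1.45, Myd88 fell by 1.26, median -1.26, and 15 lower adjusted over the list alone), and 8 of 21 microglial markers fell while H2-Aa, detected on 1 of 3 STZ arrays, rose to 8.60 (median of the list -0.73, and 2 higher and 15 lower adjusted over the list alone). The adjusted p was 0.42 with an estimated correlation for each of these lists. The microglial counts include P2ry12 among the falls and H2-Aa as the rise, both probes of the set of 112. Of 23 STAT3 targets, 4 fell, among them Socs3, Irf9 (fell by 1.30) and Atf3 (fell by 1.36), and Il6st, also of the set of 112, rose, with a median of -0.53 (adjusted p = 0.42 with an estimated correlation, and 3 higher and 13 lower adjusted over the list alone). Of 4 feeding-raising peptides Pmch, Gal and Hcrt rose (median 1.04), and of 13 feeding-lowering peptides Cartpt and Bdnf rose (median 0.37), each list at an adjusted p of 0.42 with an estimated correlation, and 3 and 4 higher adjusted over the list alone. Bdnf had an adjusted p in limma of 0.074 with the replicate number as a block and 0.053 with only the groups compared. The feeding-raising list had an adjusted p of 0.054 without STZ replicate 1, and Bdnf (0.70 ± 0.14) had 0.054 to 0.096 without any 1 sample other than STZ replicate 1 and leptin replicate 8, and 0.11 with the mean of all probes of a gene.

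The choroid plexus list had a median of -1.04, but it varied between libraries of a group. Its members lay at a median of -1.04 from saline in STZ replicate 1, within the -1.22 to -0.82 of the leptin libraries, at 0.43 and -0.01 in the other STZ libraries, and at -0.51 and 0.51 in the saline ones. Among them Lbp fell by 1.98 ± 0.36 (adjusted p = 0.65 for the list with an estimated correlation, and 0.065 for Lbp without STZ replicate 3). The mitochondrial respiratory chain list of 60 genes had a median of 0.35 with 0 members passing (Atp5o 0.66 ± 0.19), at an adjusted p of 0.69 with an estimated correlation and 0.29 without STZ replicate 1. The 46 ribosomal protein genes had a median of 0.27 with 0 passing, at an adjusted p of 0.79 with an estimated correlation, and 0.064 and 0.078 without leptin replicates 6 and 7. Without STZ replicate 1 their mean difference was -0.0039 (adjusted p = 0.71). With array weights the adjusted p of the ribosomal list was 0.12. Ppargc1a fell by 0.74 ± 0.14 in the fatty acid oxidation list (median -0.19, adjusted p = 0.60 with an estimated correlation, and 2 lower adjusted over the list alone) and Hk2 fell by 1.03 ± 0.18 in the glycolysis list (median -0.14, adjusted p = 0.65 with an estimated correlation). The adjusted p of the fatty acid list was 0.071, 0.13 and 0.068 without STZ replicate 3, leptin replicate 6 and leptin replicate 7, and that of the glycolysis list 0.27, 0.069 and 0.096 without STZ replicate 1, leptin replicate 6 and leptin replicate 7. Under median centring and with array weights the glycolysis list had 0.25 and 0.15, and with the mean of all probes of a gene the fatty acid list had 0.068. The adjusted p of Ppargc1a was 0.051, 0.067 and 0.076 without STZ replicate 2, leptin replicate 6 and leptin replicate 7, and that of Hk2 was 0.051 without leptin replicate 6. Among 3 Y-linked genes Eif2s3y, of the set of 112, rose (median 0.41, adjusted p = 0.42 with an estimated correlation and 0.055 without STZ replicate 1, and 0.49 among probes detected under 0.01 on all arrays).

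Altogether 870 probes passed in limma, 336 higher and 534 lower with leptin, for 614 genes. The count was 548 without STZ replicate 2, 482 without STZ replicate 3, 569 without leptin replicate 6, 528 without leptin replicate 7, 1861 with array weights, 552 among probes detected under 0.01 on all arrays and 169 with STZ replicate 3 taken as saline (137 higher and 32 lower). Of 38 lists 12 passed, and 0 with an estimated correlation in camera (3 at an unadjusted p under 0.05, and 9 in fry), and 6 of the 10 splits of the 6 samples, the real one included, passed at least 12 lists.

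**Figure D2:**
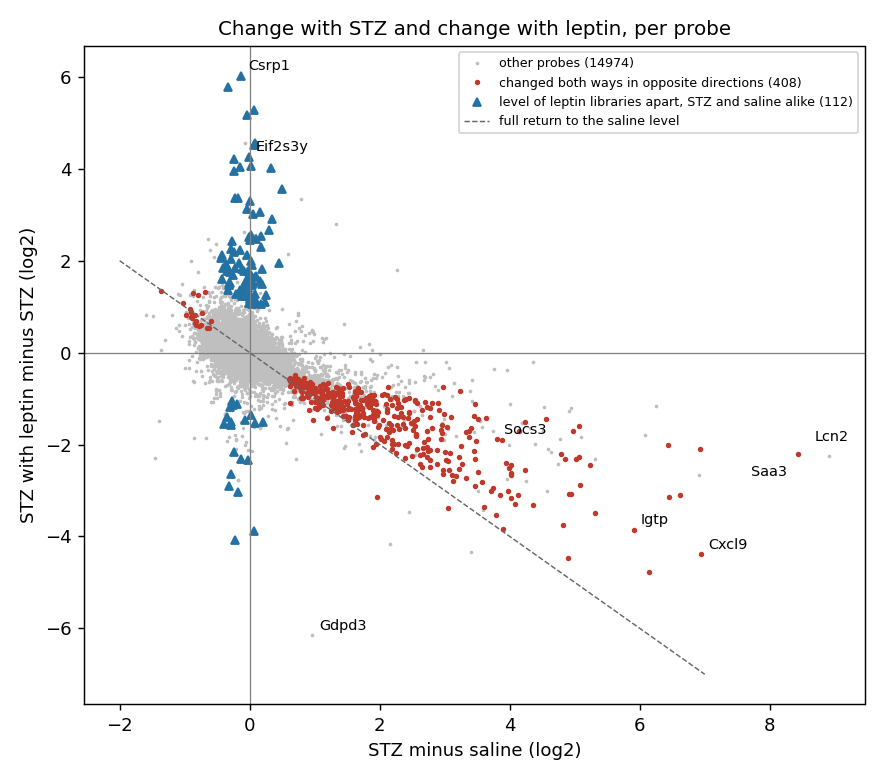
Log2 difference STZ minus saline against STZ with leptin minus STZ for each kept probe. Red points are the 408 reversed probes, blue triangles the 112 probes at 1 level in STZ and saline and another with leptin. The dashed line marks a full return to saline.

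Of the genes changed in diabetes, 323 were reversed in the leptin group, through 408 probes. Of these probes 387 were higher in STZ and lower with leptin (Igtp, Ifi47, Irgm2, Gbp3, Cd274) and 21 were lower in STZ and higher with leptin. Cd274, which encodes the immune checkpoint ligand PD-L1, rose by 3.97 ± 0.23 and fell by 3.01 ± 0.21. The MHC class II activator Ciita, detected only on the STZ arrays, rose at least 2.55-fold and fell at least 2.54-fold, and 2 probes passed both comparisons with the same sign.

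The return toward saline was partial. Of the 617 probes that rose in STZ, 608 (98.5 percent) had a lower mean with leptin, against a mean of 52.4 percent (46.5 to 56.6) in data simulated with the STZ changes and no effect of leptin. Their median rise of 1.76 log2 units was 0.62 with leptin, and the median share of the rise left was 37.4 percent, against 99.3 percent simulated. Of the 48 that fell, 43 (89.6 percent) had a higher mean with leptin, against 67.2 percent (50 to 82.9) simulated, with a median of -0.77 in STZ and -0.29 with leptin. The STZ changes given to these simulations were fitted ones of probes selected for passing, and selection can enlarge them. The simulated return may therefore be too small. Data simulated without group effects gave 0 reversed probes by the same rule in limma. A probe without a group effect has little prospect of passing both comparisons. This count therefore does not measure what the shared STZ arrays add when STZ effects exist. At an unadjusted p under 0.05 in both comparisons, 1279 probes had opposite signs, against a mean of 154.01 and a highest count of 185 in the simulations. Across all probes the changes correlated at -0.65, against -0.45 from the shared STZ samples alone, and 70.1 percent had opposite signs, against 64.7 percent. Part of the excess may come from variation shared by the STZ samples that the simulation does not hold. The leptin animals may also differ in strain from the others, and strain and group cannot be separated here. Whether leptin itself caused the return therefore stays open. The reversed count was 698 without STZ replicate 1, 234 without STZ replicate 2, 204 without STZ replicate 3, 192 without saline replicate 4, 210 without saline replicate 5, 249 without leptin replicate 7, 931 with array weights, 211 among probes detected under 0.01 on all arrays and 0 in limma with STZ replicate 3 taken as saline.

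In STZ with leptin against saline (n = 3 and 2), part of the genes that rose in STZ remained higher, 127 of the 617 probes. Lcn2 was at least 72.9-fold higher (adjusted p = 0.0019 in limma), Saa3 74.7-fold (6.22 ± 0.51), the B cell chemokine Cxcl13 34.0-fold (5.09 ± 0.40), and the Fc receptor Fcgr4 at least 18.4-fold. Socs3 remained 3.77-fold higher (1.92 ± 0.34, adjusted p = 0.022). Its adjusted p was 0.051 without STZ replicate 3, 0.22 and 0.16 without saline replicates 4 and 5, 0.074 and 0.058 without leptin replicates 6 and 7, 0.069 in the authors' processed values, 0.070 without background correction and 0.053 without a detection filter. Irf1 differed by 0.77 ± 0.20 (adjusted p = 0.12, and 0.039 with array weights) and Tap2 by 0.38 ± 0.21, without passing in the main fit. P2ry12 was lower by 2.46 ± 0.22 and Cxcl12 was lower by 1.34 ± 0.16 (P2ry12 through its probe of the set of 112), with an adjusted p of 0.14 for Cxcl12 with the mean of all probes of a gene.

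Members of the feeding lists did not pass singly against saline over all probes, and 2 of 4 feeding-raising peptides were higher when adjusted over the list alone. Gal differed by 1.42 ± 0.32 (adjusted p = 0.066, and 0.042 without STZ replicate 1, 0.048 without leptin replicate 8, 0.048 with normexp and 0.010 with array weights), Pmch by 0.49 ± 0.18, Hcrt by 0.49 ± 0.32, Npy by 0.50 ± 0.39, Cartpt by 0.18 ± 0.29 and Pomc by 0.38 ± 1.40, and Ucn, detected on 1 of 3 leptin arrays, stood at 5.20 against 6.50 (adjusted p = 0.25). The 4 feeding-raising peptides passed as a list with a median of 0.49 (adjusted p = 0.73 with an estimated correlation and 0.072 without saline replicate 4).

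By list, 8 of 21 microglial markers were higher, among them C1qb (2.49 ± 0.19) and C1qc (2.23 ± 0.18), and P2ry12 was lower (P2ry12 and the higher H2-Aa through probes of the set of 112), with a median of 1.43 (adjusted p = 0.35 with an estimated correlation, and 14 higher and 1 lower adjusted over the list alone). Of 26 interferon and MHC class I genes 8 were higher, including H2-T23 (2.83 ± 0.20), with a median of 0.81 (adjusted p = 0.66 with an estimated correlation, and 13 higher adjusted over the list alone). The H2-T23 probe used stood at 6.75 in saline, 9.77 in STZ and 9.57 with leptin. Another H2-T23 probe, of the set of 112, stood at 4.36, 4.69 and 8.71, so the probes of this gene disagree. Of 24 cytokine and NF-kB genes 7 were higher and Cxcl12 lower, with a median of 0.85 (0.63 at the bound, adjusted p = 0.73 with an estimated correlation, and 10 higher and 1 lower adjusted over the list alone). STAT3 targets had 3 higher of 23, among them Il6st (through its probe of the set of 112, detected on 1 of 2 saline arrays) and Socs3, and a median of 0.25 (0.24 at the bound), and glucocorticoid-induced genes had 2 higher of 25, 1 of them Lcn2, and a median of 0.36 (adjusted p = 0.73 with an estimated correlation for each, and 4 and 2 higher adjusted over the list alone). The STAT3 list had an adjusted p of 0.12 among probes detected under 0.01 on all arrays. The choroid plexus list had a median of -0.86 (-0.82 at the bound) and the list of GABA and glutamate signalling -0.26 (-0.24 at the bound), each with 0 members passing and an adjusted p of 0.73 with an estimated correlation, and 2 choroid plexus genes were lower when adjusted over the list alone. The ribosomal list had a median of 0.29 with 0 passing (adjusted p = 0.86 with an estimated correlation). Without saline replicate 4 the adjusted p was 0.060 for GABA and glutamate signalling and 0.24 for the ribosomal list.

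In this comparison 318 probes passed in limma, 255 higher and 63 lower, for 227 genes. The count was 109 without saline replicate 4, 128 without saline replicate 5, 714 with array weights, 183 among probes detected under 0.01 on all arrays and 153 with STZ replicate 3 taken as saline. Of 38 lists 9 passed, 5 with STZ replicate 3 taken as saline, 2 in fry and 0 with an estimated correlation in camera (2 at an unadjusted p under 0.05).

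**Figure D3:**
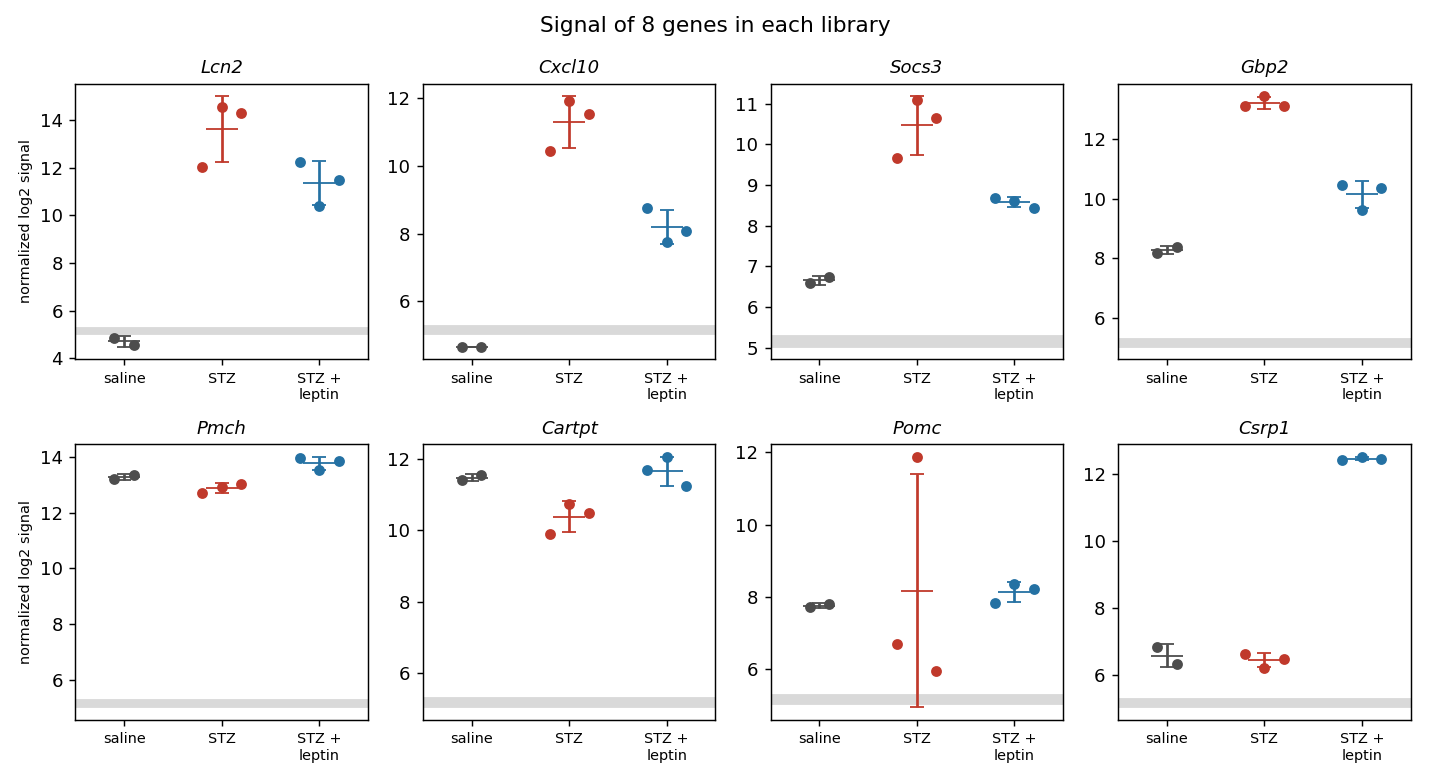
Normalized log2 signal of 8 genes in each library, with the mean and standard deviation of each group. The grey band spans the lowest detected level over the arrays. Pomc is high in STZ replicate 2 alone, and Csrp1 is high with leptin alone.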

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

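No alternative was added after the data were seen, and each one was chosen before the data were examined. The counts moved most with the samples used and their weights and with the group of STZ replicate 3. Counts are given in the order STZ against saline, STZ with leptin against STZ, STZ with leptin against saline, and reversed probes, beside 665, 870, 318 and 408. Probes detected under 0.01 on all 8 arrays gave 332, 552, 183 and 211. Array weights, which favoured STZ replicate 3 (2.49) over STZ replicate 1 (0.28), gave 1662, 1861, 714 and 931, with 14 lists in STZ against saline in place of 9, and Pomc at -0.58 against saline and 0.92 with leptin against STZ. The described replicate number as a block gave 337, 478 and 202 for STZ against saline, leptin against STZ and reversed probes, and Kdm5d at -0.088 with leptin against STZ, although samples of the same number shared no pattern (correlations of their deviations -0.22 to 0.09). With STZ replicate 3 taken as saline, limma passed 0 (893 at an unadjusted p under 0.05), 169, 153 and 0, and 5 lists with leptin against saline in place of 9, and 32 of 160 called gene results and 21 of 30 called list results passed, against 149 and 30 with the authors' processed values. Npy then differed by -0.044 in STZ against saline, and with leptin against saline Irf1 by -0.38, Cd274 by -0.31, Gbp2b by -0.46, Gbp5 by -0.32, Gbp10 by -0.53, Tap2 by -0.39, Hcar2 by -0.44, Batf2 by -0.97, Gbp7 by -0.48, Parp14 by -0.091 and Ciita by -0.32. Median centring moved the median of all probes in STZ against saline from -0.09 to -0.19 and gave Trh -0.027 with leptin against saline. Camera with an estimated correlation passed 0, 0 and 0 lists (6, 3 and 2 at an unadjusted p under 0.05), and fry passed 2 lists with leptin against saline. Leaving out 1 sample gave 277 to 1032 probes in STZ against saline, 482 to 1238 with leptin against STZ, 109 to 426 with leptin against saline and 192 to 698 reversed, with the lowest without saline replicate 4 or STZ replicate 3 and the highest without STZ replicate 1, and 8 to 18 lists in STZ against saline. The mean difference of the ribosomal list with leptin against STZ ranged from -0.0039 to 0.44. Npy ranged from -0.0033 to 0.60 in STZ against saline and from -0.10 to 0.57 with leptin against STZ, Pomc from -1.44 to 1.52 and from -1.15 to 1.82, and Kdm5d from -0.038 to 0.36 with leptin against STZ. With leptin against saline Cartpt ranged from -0.017 to 0.39 and Trh from -0.14 to 0.24. A fit without 1 saline sample takes the spread of the other groups for the single one left.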

Other observations

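The tests of neighbouring genes, of the size of shifts under other processing and of sample splits were written before their results were seen, and the tests of other probes of a gene, of the direction of shifts, of blood, neurons, microglia and pituitary tissue only after.

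A set of 112 probes, for 96 named genes and 10 probes without a symbol, stood at 1 level in STZ and saline and at another with leptin (92 higher, 20 lower, at least 1 log2 unit from both and at most 0.5 between STZ and saline), such as Csrp1, Pdrg1 and Prkag2, and made up 12.9 percent of the calls of leptin against STZ. In the 32 genes with another kept probe, the other probes followed with a median ratio of only 0.074, against 0.757 for genes changed between STZ and saline. However, 6 genes, among them Klc1, Fgf1 and Wdr46, had 2 probes in the set. Of the 48 other kept probes, 7 passed both comparisons in the same direction, and of the 42 outside the set 1 did. Genes of the set formed 26 neighbouring pairs along the chromosomes, against a median of 15 and a 95th percentile of 21 in 10000 random sets, so sequence variants under the probes, in stretches of the genome that differ between the mixed-strain animals of the groups, are a candidate source, while genes whose probes moved together may differ in expression, and whether leptin itself moved any of these genes stays open because strain and group cannot be separated here. Background correction changed the size of the shifts, with 58.0 percent of the set still meeting its definition under the least favourable of 5 other processings, where log2 differences shrink without background subtraction, but 90.2 percent or more passed both comparisons in the same direction. Outside the set, 758 calls of leptin against STZ and 206 of leptin against saline remain, and a strain difference could reach those as well. The same limit holds for the reversed probes.

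The rise of immune genes in STZ might come from blood, from a lower share of neurons or from more microglia of unchanged makeup. Red cell genes differed by a median of 0.59 log2 units, and 4 of 5 lay under the interferon median of 2.87 by more than 2 standard errors, so more blood of unchanged makeup does not account for that rise. The highest median among astrocyte, oligodendrocyte and endothelial markers was 0.0094, against 1.90 for microglia, so a loss of neurons alone would not give it. Of 21 microglial markers 57.1 percent lay over 3 standard errors from their median (C1qc 2.97, P2ry12 -0.13), so the markers did not rise alike. The size of a log2 rise also depends on the background and range of each probe. The list mixes microglial with macrophage markers, and H2-Aa among them was undetected in saline. This test therefore cannot separate changed regulation from more cells of the same makeup, and both stay open. White cells entering the tissue stay open. S100a8 and S100a9 lay at least 15.7-fold and 7.06-fold above saline without passing in the main fit, and passed with array weights (adjusted p = 0.0015 and 0.0083 in limma). Those weights were estimated from the same arrays and rest the STZ mean largely on replicate 3 (2.49, against 0.28 and 0.67 for replicates 1 and 2). Infection, housing or handling that differed between the groups was not tested.

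STZ replicate 2 held the highest signal of all 6 measured pituitary markers, with Gh at 14.98 and Prl at 14.93. The likely source is pituitary tissue in that dissected block, and the pituitary also makes Pomc, which stood at 11.88 there. This may hide a lower Pomc in STZ, since Pomc differed by -1.44 from saline without that sample.

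The 6 samples of STZ and of STZ with leptin can be split 10 ways, too few for a share under 0.05. The real split passed 870 probes and the highest other 0 in limma (279 to 1429 at an unadjusted p under 0.05, against 3002), so 1 of the 10 splits passed as many probes. For gene lists the real split passed 12 and the highest other 18, and 6 of the 10 splits passed as many lists.

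The class II genes H2-Ab1 and Cd74 were looked at after their values were seen. The highest rises in STZ were 5.10 among the probes of H2-Ab1 and 5.02 among those of Cd74, while H2-Aa stood at 5.04 in STZ, detected on 1 of 3 arrays, and 8.60 with leptin, and H2-Eb1 at 6.08 and 8.87. H2-Aa and H2-Eb1 were undetected in saline. The probes of H2-Ab1 went the other way with leptin, to means of 8.38 to 9.76, against 10.10 to 12.36 in STZ. The H2 genes lie in the MHC, which differs between strains, and whether the probes explain the pattern was not tested.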
